A study of Mus musculus with 6 samples.

How the data were processed

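The series measured gene expression in the cerebellum of mice at postnatal day 11 with Affymetrix Murine Genome U74Av2 arrays, 1 array per sample. Per the labels, 3 arrays came from mice without L1cam, a neural cell adhesion molecule encoded on the X chromosome, and 3 from wild type siblings of the same strain, 129S2/SvPasCrlf. The labels call the knockouts male and give no sex for the wild type mice. Total RNA was extracted with a column kit and labelled with biotin, per the labels' protocols, and all arrays were handled by 1 core facility.

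The deposited values are log2 expression values made by the authors with RMA, per the submitters' processing notes, which corrects background, normalizes between arrays and summarises the probes of a probe set. The RMA version and settings are not given in the sources used here, and neither is a genome build, so no coordinates are printed. Because RMA pulls the arrays towards 1 distribution, an overall change in RNA amount per cell cannot be read from these values. The scanner files were not used here.

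The table held 12488 probe sets, of which 66 array controls were left out and 12422 were tested. Gene symbols came from the annotation table supplied for the array. It gave 1 symbol for 10833 probe sets, several for 396 and none for 1193, and genes were named only from probe sets with 1 symbol. Of the 10833, the gene identifiers of 10817 were found in a RefSeq gene table of assembly GRCm38.p6, used for names only, and no symbol changed. Arrays carry no read depth. The number of arrays limits the precision, and the 95% interval of a log2 difference reached 0.158 to either side at the median. Correlations between arrays over all probe sets ran from 0.9948 to 0.9974, and no 2 arrays held the same values. The series' design text counts 3 mice per genotype, so each array was taken as 1 mouse.

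Differences were tested with limma 3.58.1 in R 4.3.3 on the values as deposited, with genotype as the term, lmFit and eBayes, 2-sided, and Benjamini-Hochberg adjustment over the 12422 probe sets at a threshold of 0.05. L1cam was also tested with an exact permutation test, which cannot go below 0.1 with 3 arrays against 3. A total of 29 gene lists for cell types, pathways and the L1 family were tested with limma's camera at a preset correlation of 0.01 between genes, with 1 probe set per gene, the one with the highest mean, over 8251 genes. Camera with an estimated correlation and fry were run beside it. Of 914 listed symbols, 5 were not found in the RefSeq table. Some genes stand in more than 1 list.

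The tests of genotype, the gene lists and most alternatives were fixed before the data were examined. Cyclic loess normalization, the difference between the 3' and 5' Gapdh control probe sets as a covariate, and camera with an estimated correlation for lists called only in another fit, and for the cell cycle list with the replicate block, were added after seeing the data. The genes to be named were L1cam, Chl1, Nrcam and Nfasc, then in each direction the 12 probe sets with 1 gene name and the largest change past the threshold. Where fewer passed, the 12 were filled with the smallest unadjusted p among those differing at least 1.5-fold, then at any fold, and from each list the 3 members with the smallest unadjusted p were taken. Nfasc has no probe set with a single symbol and is not reported.

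The count of probe sets was recomputed under 17 other settings and the count of lists under 18. These covered quantile normalization, median centring, cyclic loess, a filter at the 40th percentile of mean level, a trended robust variance, array weights, the replicate number as a block, the Gapdh covariate, each array left out, 1 value per gene, probe sets open to cross-hybridization left out, a threshold of 0.1, and other list tests. A list's direction is camera's direction against all other genes, so it can turn while the median keeps its sign. Fry's direction is against no change. Every turn of direction is counted, also where neither value passed. That rule, the reading of the control probe sets, the relations between lists, the count of splits after other scalings and nearly all tests of explanations were set after seeing the data. The Xist covariate planned for wild type arrays of mixed sex was not run, because Xist differed by only 0.048 log2 among them, under the 1 log2 set for it.

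The procedure was tested on simulated data for 12422 probe sets, 3 arrays against 3, with variances drawn from limma's fitted prior and 200 probe sets changed. It called 93% of those changed 1.5-fold and 100% of those changed 2-fold, with 11 false calls. A list shifted by 0.2 log2 had a camera adjusted p of 1.57e-22, and 1 of the other lists was also called. Simulated genes varied independently of each other, so this does not test camera where genes vary together. In the real data a probe set that stands alone needs a difference of about 0.64 log2 at the median standard error to pass. Relations between list medians across arrays used exact permutation over 720 orders. Python 3.11.15 with scipy 1.17.1 and matplotlib 3.10.9 was used for these and the plots.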

Results

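Gene expression was measured in the cerebellum of 3 L1cam knockout mice and 3 wild type siblings at postnatal day 11, an age at which granule neurons are still being born and myelin is forming. L1cam is a cell adhesion molecule of growing axons. The comparison asks which transcripts differ in the cerebellum when it is missing. Values are RMA log2 values of 12422 probe sets per array. Array medians ran from 8.87 to 8.94, and values within an array from 5.08 to 15.47.

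L1cam, the targeted gene, had the smallest unadjusted p-value of all probe sets and lay lower in all 3 knockout arrays than in any wild type array. Its probe set read 8.06 ± 0.17 (SD, n = 3) in the knockouts and 8.66 ± 0.16 (SD, n = 3) in wild type. The difference was -0.60 on the log2 scale (SE 0.10, 95% interval -0.83 to -0.38), or 1.52-fold lower in the knockouts. It did not pass in limma (adjusted p = 0.841), and the 2-sided exact permutation p was 0.1, the smallest that 3 arrays against 3 allow. Adjusted over the list alone, among 27 genes of the L1 family and its binding partners, L1cam had a limma adjusted p of 0.00402. The altered part of the gene and the position of the probes are not given in the sources used here, so a remaining signal of 8.06 does not bear on whether the protein was lost, and the probe set is only a partial check of the labels.

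The other L1 family members did not pass either. Chl1, the close homolog of L1, differed by -0.18 (95% interval -0.36 to 0) at one probe set and by -0.09 at another. The latter lay near the bottom of the range, at percentile 0.97 of mean level. Nrcam, an adhesion molecule of nodes of Ranvier, differed by -0.057 (95% interval -0.25 to 0.14), and by 0.041 without wild type 3. Of the 27 family and partner genes measured, 9 had a higher and 18 a lower knockout mean, with a median of -0.039. Ank3, the ankyrin that anchors L1 family proteins to the cytoskeleton, differed by -0.22 and Ncam1 by 0.17. Of 19 kinases and partners in L1 signalling, 6 were higher and 13 lower (median -0.039), with Pik3r1, a regulatory subunit of PI3 kinase, at -0.19, Fyn at 0.13 and Rps6ka3 at 0.12. The Rps6ka3 probe set also lay near the bottom of the range (percentile 1.6). Neither list passed camera (adjusted p = 0.502 and 0.633).

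**Figure D1:**
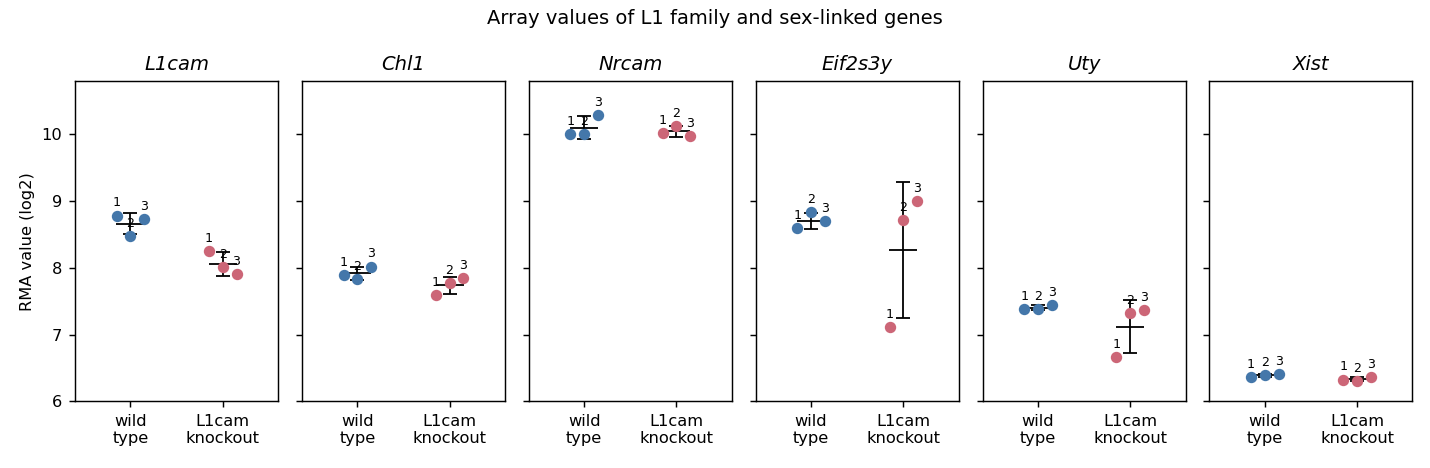
RMA log2 values of L1cam, Chl1, Nrcam, Eif2s3y, Uty and Xist in each array, with wild type in blue, knockout in red, numbers giving the replicate, and bars the mean and SD of 3 arrays. L1cam lies lower in every knockout array than in every wild type array, and knockout 1 reads 7.11 for Eif2s3y where the other 5 arrays read at least 8.59.

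Across the array, no probe set passed an adjusted p of 0.05 in limma, and the smallest adjusted p was 0.841. At an unadjusted p under 0.05 there were 631 probe sets, 305 higher and 326 lower in the knockouts, where 621.1 are expected by chance. L1cam was the only probe set that also differed by at least 1.5-fold at an unadjusted p under 0.01. The groups did not overlap for 1291 probe sets, or 10.4% against the 10% chance gives. The split between higher and lower depended on scaling: of those at an unadjusted p under 0.05, 48.3% were higher as deposited, 66.0% after quantile normalization, 79.1% after median centring and 66.3% after cyclic loess, a setting added after seeing the data. Leaving out knockout 3 gave 1 probe set past the threshold, for Sox11.

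The 12 probe sets with the smallest unadjusted p among those higher in the knockouts covered 11 genes, none past the threshold. Cirbp, the cold-inducible RNA-binding protein, differed by 0.53 (SE 0.10). Srsf5, a splicing factor, differed by 0.38 (SE 0.08), and Hnrnpdl, a ribonucleoprotein, by 0.40 and 0.32 at 2 probe sets but by -0.043 at another. Cnbp, a nucleic acid-binding protein, differed by 0.34 at one probe set, by 0.26 at another and by -0.024 at the third. Ddx3x, an X-linked RNA helicase, differed by 0.38, and by 0.26 and -0.13 at its other probe sets. Snhg5, a host of small nucleolar RNAs, differed by 0.49 (SE 0.09). Txnip, which binds thioredoxin, differed by 0.44, yet by -0.078 at another probe set. The others were Sumo3 at 0.34, the deubiquitinase Usp22 at 0.28, the flap endonuclease Fen1 at 0.28 and the arginase Arg2 at 0.27, the last differing by 0.017 at another probe set.

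Lower in the knockouts, and likewise none past the threshold, were L1cam and 11 other genes. Several of these probe sets were dim, with percentiles of mean level of 7.9 for Sfpq, 18.4 for Nectin3, 18.95 for Zfp758 and 19.7 for Bdnf. Others lay higher, up to 72.2 for Trio. Sox11, a transcription factor of immature neurons, differed by -0.52 (SE 0.13) at one probe set and by -0.41 at another. Without knockout 3 the first of these was -0.69 with a limma adjusted p of 0.0447, and over all alternatives its adjusted p ran from 0.0447 to 1. Bdnf, a neurotrophin, differed by -0.26 (SE 0.06), and Nectin3, an adhesion molecule, by -0.37 at one probe set but by -0.021 at another. Trio differed by -0.25. Among chromatin and transcription genes, Chd8 differed by -0.28, Zmynd8 by -0.42, Rprd1b by -0.45 (-0.10 at another probe set), Zfp758 by -0.34 and Zfp322a by -0.42. Agfg1 differed by -0.33, and by -0.22 and -0.12 at its other probe sets. Sfpq, a splicing factor, differed by -0.33 at one probe set, while its 4 other probe sets lay between -0.107 and 0.026.

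**Figure D2:**
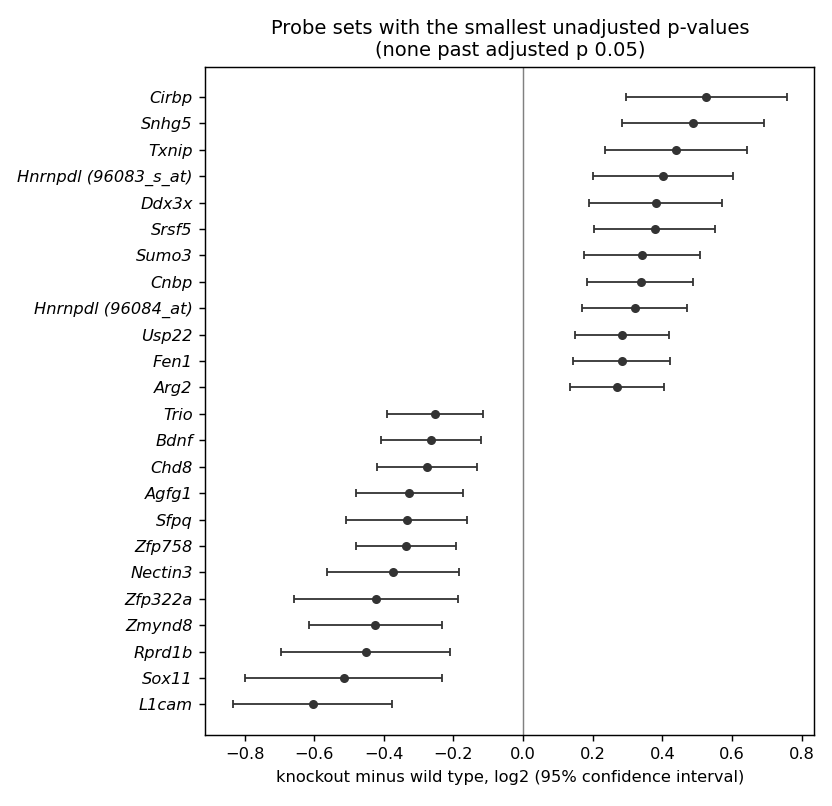
Difference between knockout and wild type in log2 units with its 95% interval for the 24 probe sets with the smallest unadjusted p-values, 12 in each direction. The differences run from -0.60 for L1cam to 0.53 for Cirbp, and none passed an adjusted p of 0.05.

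Of the 29 gene lists, 1 passed camera, and the adjusted p of the other 28 ran from 0.103 to 0.98. The median over all genes in the list tests was -0.022, and 22 of the 29 list medians lay below 0. List medians and counts of higher and lower genes, above and below, are to be read against that value and not against 0. A small negative median is therefore not in itself a fall particular to a list. Genes of the cell cycle and DNA replication were shifted upward in the knockouts against the other genes (adjusted p = 0.0123), with 25 of 40 higher, 15 lower and a median of 0.051. With an estimated correlation the same list had adjusted p = 0.925, and fry gave adjusted p = 0.87. No member passed, over all probe sets or adjusted over the list alone. Mad2l1, a spindle checkpoint protein, differed by 0.32, Hmgb2, a chromatin protein of dividing cells, by 0.47 and Chek1, a checkpoint kinase, by -0.19. The median deviation from the mean of 6 arrays was 0.159 in knockout 1 and 0.080 in wild type 1, and lay between -0.128 and -0.018 in the other 4. Knockout 1 also had the largest gap between the 3' and 5' Gapdh control probe sets, 0.67 against at most 0.13 elsewhere. The call ended without knockout 1 (median -0.008, adjusted p = 0.991), without wild type 2 (median 0.045, adjusted p = 0.121), without wild type 3 (median 0.002, adjusted p = 0.518) and after median centring (median 0.083, adjusted p = 0.075). With the Gapdh difference as a covariate, added after seeing the data, the median was -0.021 (adjusted p = 0.737). This covariate mainly marks knockout 1, so the fit comes close to leaving that array out and is not a separate check of RNA quality.

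**Figure D3:**
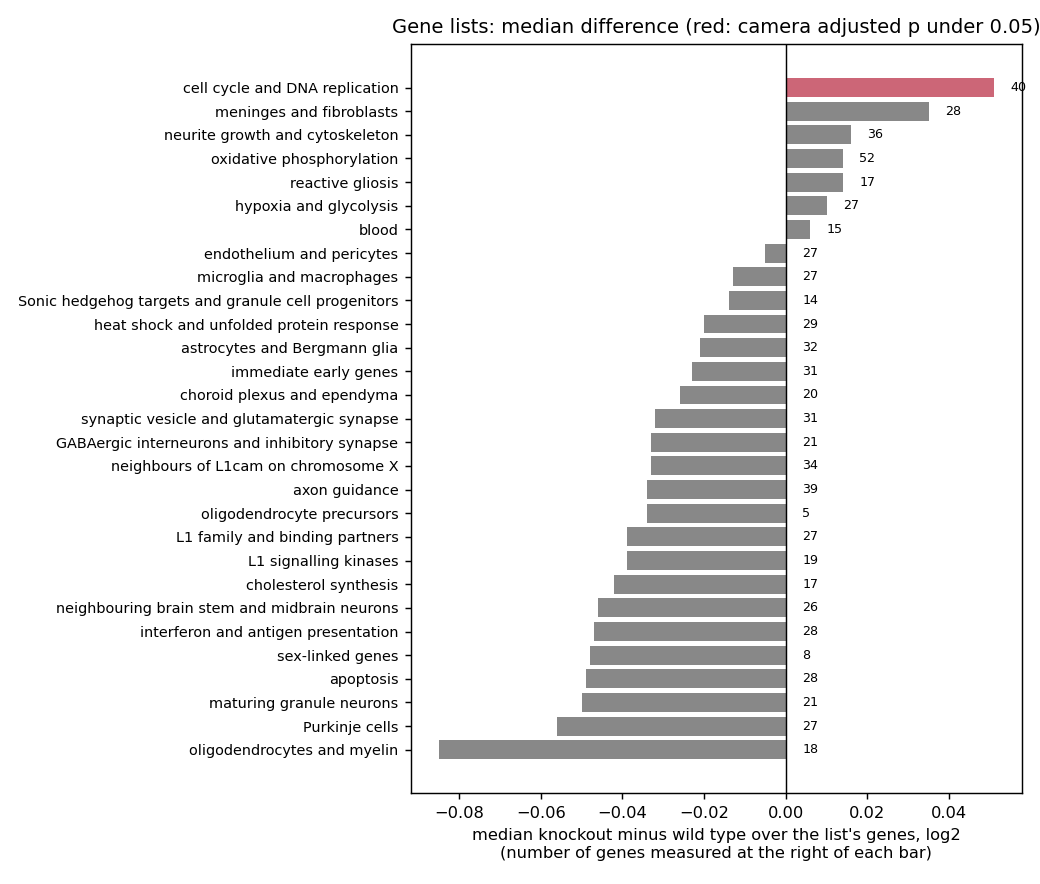
Median difference between knockout and wild type in log2 units over the genes of each of the 29 lists, with the number of genes measured beside each bar. The median over all genes in the list tests was -0.022. The cell cycle list, in red, has a median of 0.051 and is the only one with a camera adjusted p under 0.05, a call that is lost with an estimated correlation.

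The lists of cerebellar neurons did not pass. Granule cell progenitors and Sonic hedgehog targets, the dividing cells of the external granular layer, had 6 of 14 genes higher and a median of -0.014, which was 0.018 after median centring, with a mean of 0.001. Median centring moved every difference by the same amount, and the median over all probe sets went from -0.0229 to 0.0089. Changes of sign after median centring, here and below, are therefore not particular to a list. Ptch1, the hedgehog receptor, differed by -0.28, Atoh1 by -0.13 and Mycn by 0.23. Of 21 genes of maturing granule neurons, 6 were higher and 15 lower (median -0.050), with Nfia at -0.15, En2 at -0.18 and Pax6 at 0.17. Of 27 Purkinje cell genes, 7 were higher and 20 lower (median -0.056, camera adjusted p = 0.249), with Cck at -0.26, the calcium pump Atp2b2 at -0.27 and the calcium channel Cacna1g at -0.23. The Purkinje list passed without wild type 1 (median -0.097, adjusted p = 0.00116) and without knockout 3 (median -0.080, adjusted p = 0.0132). With an estimated correlation these were adjusted p = 0.692 and 0.645. Without knockout 1, the array with the largest Gapdh gap, the Purkinje median was -0.008 (adjusted p = 0.991), and over all single omissions it ran from -0.097 to -0.008. Of 21 genes of inhibitory neurons and synapses, 3 were higher and 18 lower (median -0.033), with Gabra2 at -0.16, Sst at -0.12 and Npy at -0.097. Of 26 genes of neighbouring brain stem and midbrain neurons, 4 were higher and 22 lower (median -0.046), with Hoxb3 at -0.14 and Prph at -0.12.

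Glial lists did not pass either. Of 18 oligodendrocyte and myelin genes, 5 were higher and 13 lower, with a median of -0.085 (camera adjusted p = 0.393) that was -0.025 without knockout 1. Mal, a myelin proteolipid, differed by -0.24, Nkx2-2, a transcription factor of the lineage, by -0.18 and Qdpr by 0.15. Of 5 oligodendrocyte precursor genes 2 were higher (median -0.034), with Pdgfra at 0.17 and Vcan at -0.13. Of 32 genes of astrocytes and Bergmann glia 12 were higher and 20 lower, with a median of -0.021 that was 0.010 after median centring. Aqp4, the water channel of astrocyte endfeet, differed by -0.37, Ntrk2 by -0.26 and Sparc by 0.25. Reactive gliosis genes had a median of 0.014, with 9 of 17 higher, and Ccl2 at -0.17. Of 27 microglial genes 11 were higher, with a median of -0.013 that was 0.018 after median centring, and Cx3cr1 at -0.11.

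**Figure D4:**
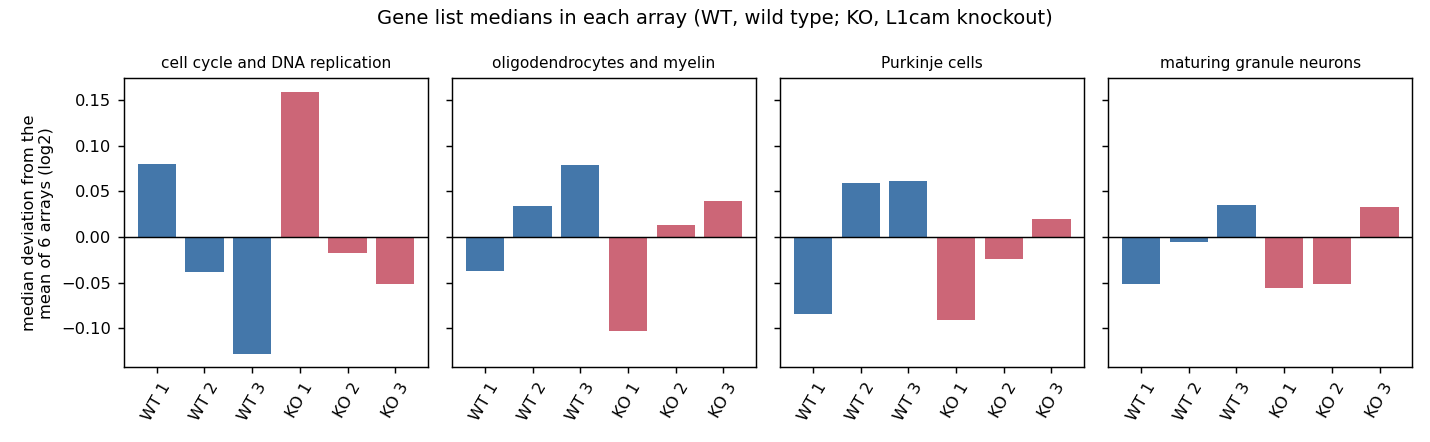
Median deviation of each array from the mean of 6 arrays, in log2 units, for 4 gene lists, with wild type in blue and knockout in red. In the cell cycle list knockout 1 reads 0.159 and wild type 1 reads 0.080, and in the myelin list the same arrays read -0.103 and -0.037.

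Lists for axons and synapses did not pass, and their negative medians lay close to the -0.022 over all genes in the list tests. Of 39 axon guidance genes 12 were higher and 27 lower (median -0.034), with the semaphorin receptor Plxna2 at -0.20, Ephb6 at -0.16 and Efnb3 at -0.14. Of 36 genes of neurite growth and the cytoskeleton 20 were higher (median 0.016), with Crmp1, a mediator of semaphorin signalling, at 0.26, Gap43, a growth cone protein, at 0.18 and Stmn4 at -0.24. This list passed without wild type 3 (median 0.034, adjusted p = 0.0152), but not with an estimated correlation (adjusted p = 0.986), and its median ran from -0.011 without wild type 1 to 0.034 over the single omissions. Of 31 genes of synaptic vesicles and glutamatergic synapses 9 were higher and 22 lower, with a median of -0.032 that was 0 after median centring. Gria2, an AMPA receptor subunit, differed by -0.37, Syt4 by 0.20 and Cask by 0.14.

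Among vascular, blood and covering tissues, blood genes had 9 of 15 higher, a median of 0.006 and a camera adjusted p of 0.103. Hba-a1, an alpha globin, differed by 0.29 and was past the threshold adjusted over the list alone (limma adjusted p = 0.0316), though not over all probe sets (adjusted p = 0.841), Hbb-b2 differed by 0.24 and Bpgm by 0.19. The blood list passed without wild type 1 (median 0.043, adjusted p = 0.00597), without knockout 3 (median 0.061, adjusted p = 0.00217) and with the mean of a gene's probe sets (adjusted p = 0.0433). With an estimated correlation these were adjusted p = 0.692, 0.645 and 0.854, and over single omissions the median ran from -0.006, without wild type 2, to 0.061. Genes of meninges and fibroblasts had 18 of 28 higher (median 0.035, adjusted p = 0.192), with the collagen chaperone Serpinh1 at 0.14 and Col4a1 at -0.13, and the list passed without wild type 1 (median 0.053, adjusted p = 0.0203, or adjusted p = 0.692 with an estimated correlation). Without wild type 3 its median was -0.005, the lowest of the single omissions. Endothelial and pericyte genes had a median of -0.005, which was 0.027 after median centring, with 13 of 27 higher and Nos3 at -0.14. Choroid plexus and ependymal genes had 5 of 20 higher and a median of -0.026, which was 0.006 after median centring. Without knockout 3 this list passed in the other direction (median 0.027, adjusted p = 0.0419, or adjusted p = 0.645 with an estimated correlation), and over single omissions its median ran from -0.079 to 0.027.

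Stress and metabolic lists did not pass. Immediate early genes had 10 of 31 higher and a median of -0.023, which was 0.008 after median centring, with Bdnf at -0.26 and Ccn2 at 0.23. Apoptosis genes had 8 of 28 higher (median -0.049), with Mcl1 at 0.17 and Diablo at -0.14. Heat shock and unfolded protein genes had 11 of 29 higher and a median of -0.020, which was 0.012 after median centring, with the chaperone Hspa4 at -0.26 and Xbp1 at -0.34. Genes of hypoxia and glycolysis had 15 of 27 higher (median 0.010), with hexokinase Hk1 at 0.20, and the list passed without wild type 2 (median 0.051, adjusted p = 0.042, or adjusted p = 0.903 with an estimated correlation). Without wild type 1 its median was -0.014. Oxidative phosphorylation genes had 31 of 52 higher (median 0.014), with Uqcrc1 at 0.15, and passed without wild type 2 (median 0.083, adjusted p = 7.39e-05) and without knockout 2 (median 0.046, adjusted p = 0.0368). With an estimated correlation these were adjusted p = 0.903 and 0.89, and without wild type 1 the median was -0.032. Cholesterol synthesis genes had 2 of 17 higher (median -0.042), with Ebp at -0.22. Interferon and antigen presentation genes had 8 of 28 higher (median -0.047), with Tap2 at -0.17 and H2-K1 at 0.13.

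Sex-linked genes had 3 of 8 higher and a median of -0.048, with Eif2s3x at 0.17. The library labelled knockout 1 stood apart in some Y-linked probe sets and not in others. Eif2s3y read 7.11 against at least 8.59 in the other 5 arrays, and Uty 6.67 against at least 7.32. Kdm5d read 7.217 against at least 7.218, and the 2 Sry probe sets read 5.93 against at least 5.81 and 9.09 against at least 9.11. The first Sry probe set lay near the bottom of the range (percentile 3.67 of mean level), so it could hardly show a fall. Xist, which is expressed from the inactive X chromosome, read between 6.31 and 6.41 in all arrays, near the bottom of the range. Of 34 neighbours of L1cam on the X chromosome 14 were higher and 20 lower (median -0.033), with Idh3g at 0.22 and Vbp1 at 0.13, and the list did not pass (camera adjusted p = 0.808). Camera's direction was up while the median lay below 0 in 6 lists: hedgehog targets, astrocytes, microglia, endothelium, sex-linked genes and neighbours of L1cam, and the mean lay above 0 in the first and the endothelial one. Adjusted over the list alone, only L1cam and Hba-a1 passed among the members of the 29 lists.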

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

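The array's control probe sets were not tested for genotype and entered only the fit with the Gapdh covariate. They compare signal at the 3' and 5' ends of a few abundant transcripts, and a larger gap accompanies shorter or degraded RNA. Over 4 controls and 3 knockout arrays, a knockout array lay above the highest wild type array in 7 cases. Cases from the same array are not independent. A given array lies above 3 others 1 time in 4 by chance, and most of the 7 gaps are small. For Gapdh, knockout 1 read 0.67 and knockout 3 read 0.13, against at most 0.12 in wild type. For Actb, knockout 1 read 1.09 and knockout 3 read 0.95, against at most 0.93. For pyruvate carboxylase, knockout 1 read 0.88, against at most 0.85. For the transferrin receptor, knockout 1 read 1.33, equal to the highest wild type at this rounding, and knockout 3 read 1.48. Gapdh in knockout 1 is the value farthest from wild type. What these gaps do to the gene lists is weighed with the cell cycle list.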

How the results depend on the processing

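Cyclic loess, the Gapdh covariate and the estimated correlation for calls made in another fit or with the block were chosen after seeing the data. L1cam stayed lower, without passing, in all 14 alternatives that measured it (-0.701 to -0.532, adjusted p 0.196 to 1). The filter at the 40th percentile removed it and gave no value. Of 374 alternative values of the other 26 named probe sets, 373 kept their sign and 1 passed. The 24 probe sets chosen by rank, L1cam among them, had groups that did not overlap. Leaving out 1 array could therefore not turn their sign, so the kept signs say little about robustness. Nrcam ran from -0.107 to 0.041 as single arrays were left out. Except where fewer probe sets were tested, or where L1cam fell short of the 1.5-fold limit, the cause was not tested for the results below.

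The count of probe sets past the threshold stayed at 0 in all but 1 of 17 settings, running from 0 to 1 as single arrays were left out. The count at an unadjusted p under 0.01 and 1.5-fold, 1 as deposited, was 0 after quantile normalization, median centring, cyclic loess and the filter (which removed L1cam), and ran from 0 to 6 without single arrays. The count at an unadjusted p under 0.05, 631 as deposited, was 401 with the filter, since fewer probe sets were tested, 1162 with array weights, and 395 to 1078 without single arrays.

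The count of lists past camera, 1 as deposited, differed in 10 of 18 settings. It was 0 after median centring, with the Gapdh covariate, with an estimated correlation and with fry, 2 with the mean of a gene's probe sets, and 0 to 4 without single arrays. Without wild type 3 the count stayed at 1, but the list was neurite growth and not the cell cycle. The 11 calls of other lists without an array or with the mean of probe sets were all lost with an estimated correlation (adjusted p 0.645 to 0.986), choroid at a median of 0.027.

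The numbers were not taken to pair the arrays, since the correlations of their deviations were 0.16, -0.32 and 0.17. Of 6 arrays, 2 correlated best with their own number. These correlations over all probe sets do not rule pairing out. From highest to lowest, the cell cycle median ranked knockout 1, wild type 1, knockout 2, wild type 2, knockout 3, wild type 3. The myelin median ranked them in the reverse order. With the replicate block, 0 probe sets and 1 list passed, 634 probe sets had an unadjusted p under 0.05, and L1cam differed by -0.604 (adjusted p = 0.196). For the cell cycle list the blocked adjusted p was 0.000824 at the preset correlation but 0.886 with an estimated one (0.925 without the block, and 0.87 by fry), with the knockout above wild type at each number (0.159 and 0.080, -0.018 and -0.038, -0.051 and -0.128). The block changed no call at the preset correlation, and the call is lost with an estimated one.

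By a rule set after the values were seen, which counts a turn in any list, directions turned 57 times, in 17 lists, where neither value passed, and the cell cycle and choroid plexus lists each turned once where one of the values passed. Values are list medians, and camera's direction is against all other genes. With the Gapdh covariate, medians were L1 kinases -0.016, Purkinje 0.011, hedgehog -0.058, cell cycle -0.021, immediate early -0.017, maturing granule -0.013, microglia -0.022, myelin -0.004 and synapse 0.014. Fry's direction is against no change, so its 5 differences come from the other null, at the medians as deposited: hedgehog -0.014, astrocytes -0.021, microglia -0.013, X neighbours -0.033 and sex-linked -0.048. With array weights they were astrocytes -0.029, choroid -0.026 and sex-linked -0.064. After median centring they were astrocytes 0.01 and sex-linked -0.017, after cyclic loess astrocytes -0.007, choroid -0.002 and oxidative phosphorylation 0.002, and after quantile normalization astrocytes -0.002, choroid -0.003 and oxidative phosphorylation 0.003. With only genes in 1 list they were astrocytes -0.021, choroid -0.021 and microglia -0.027. With the filter they were L1 family -0.032, choroid -0.02 and microglia -0.027. With the mean of probe sets choroid was -0.025, and with the block sex-linked was -0.048.

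Without single arrays, the medians of lists that turned ran from -0.057 to 0.036 for hedgehog, -0.097 to -0.01 for maturing granule, -0.091 to -0.025 for myelin, -0.102 to 0.025 for oligodendrocyte precursors, -0.045 to -0.003 for astrocytes, -0.038 to 0.018 for microglia, -0.079 to 0.027 for choroid, -0.078 to 0.002 for synapse, -0.056 to -0.001 for immediate early, -0.068 to -0.005 for heat shock, -0.032 to 0.083 for oxidative phosphorylation, -0.072 to -0.007 for interferon and -0.088 to 0.03 for sex-linked genes. Signal over background could not be judged from RMA values alone.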

Other observations

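All tests in this part were chosen after the results they bear on were seen, except the test of RNA-binding families, whose own values were unseen but whose make-up was conceived from the genes with the smallest p-values.

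Across the 6 arrays, the median of the myelin genes ran opposite to that of the cell cycle list, with r = -0.995 and exact permutation p = 0.0014, the smallest 720 orders gave, and rho = -1 with exact permutation p = 0.0028. Of 28 lists compared with the cell cycle list, this was the only one past adjustment by Pearson (adjusted p = 0.0389), the lowest value a lone list can reach here. None was by Spearman (smallest adjusted p = 0.0778), but a lone list could not pass there even at rho = -1. Without the 2 arrays farthest from the median, the myelin r was -0.988. The lists share no gene. Purkinje genes had r = -0.917 (exact permutation p = 0.0042, adjusted 0.0583) and rho = -0.943 (exact permutation p = 0.0167), with r = -0.661 without the 2 farthest arrays. In all, 6 lists had r below -0.8, and they include lists that do not mark maturity. Immediate early genes had r = -0.873 (exact permutation p = 0.0236, adjusted 0.156), rho = -0.829 (exact permutation p = 0.0583) and r = -0.929 without the 2 farthest arrays. The L1 signalling kinases had r = -0.858 (exact permutation p = 0.0278, adjusted 0.156), rho = -0.6 (exact permutation p = 0.242) and r = -0.436 without those arrays. Synapse genes had r = -0.877 (exact permutation p = 0.0347, adjusted 0.162), rho = -0.829 (exact permutation p = 0.0583) and r = -0.415 without them. Genes of maturing granule neurons had r = -0.819 (exact permutation p = 0.05, adjusted 0.2), rho = -0.986 (exact permutation p = 0.0056, adjusted 0.0778) and r = -0.748 without them. Granule cell progenitor genes ran with the cell cycle list, with r = 0.935 (exact permutation p = 0.0125, adjusted 0.117), rho = 0.829 (exact permutation p = 0.0583) and r = 0.834 without the 2 farthest arrays. The labels name no batch, and 3 arrays per genotype are too few for a test within a genotype. In each genotype, though, the cell cycle median fell and the myelin median rose from number 1 to number 3. Wild type read 0.080, -0.038 and -0.128 for the cell cycle and -0.037, 0.034 and 0.079 for myelin. The knockouts read 0.159, -0.018 and -0.051 for the cell cycle and -0.103, 0.013 and 0.039 for myelin.

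The first pattern is the upward shift of the cell cycle list. A shift present in every knockout library is not shown, since the median without knockout 1 was -0.008, but the spread between arrays (SD 0.103) is larger than the change of 0.059 and leaves it open. RNA quality of knockout 1 may contribute: the call ended without that array (adjusted p = 0.991), but without wild type 3 it ended too, with a median of 0.002, and without wild type 2 with a median of 0.045. The call thus depends on more than 1 array, but the omissions do not show that the shift comes from the arrays left out. In both genotypes the array numbered 1 was highest and that numbered 3 lowest (knockout 0.159 and -0.051, wild type 0.080 and -0.128). Leaving out 1 of these unbalances the groups. The knockout lay above wild type at each number, but the numbers were not taken to pair the arrays, so this is weak support for a shift. With the replicate block, camera with an estimated correlation gave an adjusted p of 0.886. RNA quality cannot be told apart from other differences between arrays. A candidate explanation is that the tissue of the libraries high in this list was less mature, by age within the day, dissection or growth. The 2 arrays highest in the list, knockout 1 and wild type 1, were also the 2 lowest in both the myelin and the Purkinje list (2 of 2), but this restates the relations above, which were already seen, so it decides nothing and the explanation stays open and untested.

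The second pattern is the low level of Eif2s3y and Uty, but not of Kdm5d (-0.087 from the mean of the other arrays) or Sry (-0.042 and -0.179), in the library labelled knockout 1. A fall of this size was not general in knockout 1: of probe sets at a similar level, at most 0.0387% were as far below the other arrays. Both genes were singled out for their low values there, which favours a small share. They came from a sex-linked list fixed before the data were examined, though, so that choice alone does not force falls this large. By size of fall in knockout 1, Eif2s3y ranked 2 and Uty 10 among the probe sets. Kdm5d ranked 2503, and the Sry probe sets 4639 and 638. The share does not bear on loss of particular transcripts from degraded RNA. An XX animal under a male label stays open, because Xist in knockout 1 differed from the mean of the other arrays by -0.043 and the probe set was dim in all 6 arrays, so it may not read Xist. Kdm5d was dim in all arrays too, but at a level like that of Uty, which fell (mean percentiles 20.9 and 21.9 in the other arrays). One Sry probe set was also dim in all arrays. Genes expressed from both X chromosomes went both ways (Kdm6a -0.16, Eif2s3x 0.145), so the Kdm5d, Sry and X-linked values do not settle it. A swap with a wild type library would also put a wild type array in the L1cam range of knockouts 2 and 3. None lay there: wild type read at least 8.479, and knockouts 2 and 3 read 8.010 and 7.914. The swap is still not excluded by the rule set for it, since L1cam in knockout 1 lay 0.227 below the lowest wild type array, under 2 SD. The position of the L1cam probes is also not known here. Without knockout 1, no list and no probe set passed, and 482 probe sets had an unadjusted p under 0.05.

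The third pattern is that Cirbp, Srsf5 and Hnrnpdl, genes of RNA-binding proteins, stood among the smallest p-values on the higher side. None passed, enrichment of such genes was not tested, and Sfpq, a splicing factor, stood on the lower side (-0.33). Scaling that depends on signal level is argued against as the whole cause for these genes, since 94.8% of the median difference of Cirbp, Srsf5 and 2 Hnrnpdl probe sets was left after cyclic loess (0.39 before, 0.37 after). A shift of the Srsf, Hnrnp and Rbm families without those 3 genes stays open: 22 of 35 genes were higher, with a median of 0.066 against -0.022 for all genes, but camera gave p = 0.211 with an estimated correlation, against 2.17e-05 at the preset one. Cooler tissue in the knockout pups, which might raise Cirbp, stays open as well, since 11 heat shock chaperone genes had a median of -0.006 and went both ways.

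With 3 arrays against 3 there are only 10 splits, too few to say whether chance grouped the arrays. The genotypes gave 631 probe sets at an unadjusted p under 0.05, 3 of the 10 splits gave as many, and the highest other split gave 2136. That split set wild type 1, wild type 3 and knockout 2 against the rest and gave several times the real count, which points to a structure among the 6 arrays. After quantile normalization, median centring and cyclic loess it gave 1691, 1919 and 1681, against 608, 675 and 602 for the genotypes, so these scalings did not remove it, and its source is not known. It also follows the spread of values within an array, with an SD of 1.74 to 1.75 in those 3 arrays and 1.77 to 1.79 in the others. The genotypes gave 1 list past camera, all 10 splits gave as many, and the highest other split gave 13.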
